A study of Danio rerio with 9 samples.

How the data were processed

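RNA was extracted from zebrafish (Danio rerio) larvae that the labels describe as 7 days old, after a 7-day exposure to perfluorododecanoic acid (PFDoDA, a long-chain perfluorinated carboxylic acid) or to the DMSO vehicle. There were 9 libraries, 3 per group: vehicle control (0 µg/L), low dose (0.1 µg/L) and high dose (10 µg/L). Per the labels' protocols, polyadenylated RNA was selected with oligo-dT beads, and libraries were made with a directional (dUTP) kit and sequenced on an Illumina instrument. The labels do not say whether a library is a pool of larvae or whether the libraries of a group came from separate tanks, so p-values measure only the spread between these libraries, which may be technical. The libraries are named C1 to C3 (control), L1 to L3 (low dose) and H1 to H3 (high dose) after the column headers. Titles number the low-dose samples differently from the columns, so each low-dose column was matched to its group only.

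The authors deposited 2 sheets, one per dose, each holding the libraries of that dose beside the same 3 controls. Per the file headers, the columns used here are read counts per gene. These deposited counts are whole numbers without normalization. The sheets list 25276 genes (low dose) and 25198 genes (high dose), of which 24661 are in both, and the control counts of shared genes do not differ in any cell (0 cells). The smallest gene total within a sheet is 2 counts. Each sheet also holds the authors' comparison with its control, as a log2 fold change per the file headers, and the deposited p-value and adjusted p-value of each gene. The deposited adjusted p-value is exactly 1 for 20121 genes (low dose) and 8853 genes (high dose), as many as DESeq2 left without an adjusted p in the run made here. The submitters' processing notes name fastp, HISAT2, featureCounts and DESeq2, without versions, and the genome build GRCz11. The order of the steps, the counting options and whether strand was used in counting are not given in the sources used here, so counts of overlapping and antisense genes, and of near-identical gene copies such as histone, crystallin, elastase and trypsin genes, are uncertain. In the files, 385 symbols stand on more than one gene identifier. Coordinates are those of the files. Another 28 columns (normalised values, FPKM and group means) were not used.

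Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Total counts ran from 12128785 to 13791087 per library. For each comparison the libraries of its 2 groups were used alone. Genes were filtered with filterByExpr by group, scaled with TMM factors, and tested with the quasi-likelihood test (glmQLFit, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of its F statistic. CPM values use the TMM factors of the 6 libraries compared, so the control values of a gene differ slightly between comparisons. For high against low dose, the genes in both sheets were used. The test was run on simulated counts with 200 genes changed by known amounts. Its step ran on 18751 simulated genes for the low dose and recovered 0% of genes changed by 1 on the log2 scale, 16.9% of those changed by 2 and 67.7% of those changed by 3. On 18420 simulated genes for the high dose it recovered 0%, 1.6% and 32.3%. For high against low dose, on 18959 simulated genes, it recovered 1.5%, 45.5% and 90.6%. Unchanged genes called numbered 4, 2 and 7. Under these conditions most changes of 1 on the log2 scale are out of reach at this spread between libraries.

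Before the data were examined, 37 gene lists (pathways and cell type markers that fit whole larvae and this class of compound) were fixed, holding 1705 symbols. Each list with at least 5 measured members was tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and adjusted over lists. Camera compares a list with the other genes, and fry was run beside it, which asks whether a list's genes move one way without comparing them with other genes. Camera was also run with the correlation estimated per list. List values are medians of log2 differences relative to the median of all genes tested. On simulated counts with the pancreas list shifted by 1, camera called that list in each comparison and 0 of the others. These counts were drawn independently per gene, so they do not show how often camera at its preset calls lists of correlated genes. The correlation estimated for the pancreas list in the real libraries was 0.764 at the low dose.

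Named genes followed a rule fixed in advance. With fewer than 5 genes past the threshold, it names the 10 genes with the smallest p, a symbol and a mean of at least 1 CPM, given as not past it. For lists that pass, it names the 2 members with the smallest p, given here for the lists described. A further 20 genes (among them cyp1a, cyp3a65, cpt1aa, angptl4, pdk2b, fabp1a, hmgcra, hmgcs1, fasn, cyp7a1, fabp10a, vtg1, hmox1a, gclc, sod1, il1b, cdkn1a and per1b) are always examined. Those with p under 0.05 are named and the rest counted. Some of the fixed genes and 1 of the fixed lists are in the counts but are not reported here. Chosen after their values were seen were the lists whose members are named, cel.1, fosab and sik1 at the low dose, eevs, zgc:113054, amy2a and cel.1 at the high dose, eevs and zgc:113054 between doses, and the genes drawn or given per library.

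Control and high-dose samples share the replicate numbers 1 to 3 in their titles. Deviations from the group means correlated at 0.5 for C1 and H1, 0.225 for C2 and H2, and 0.634 for C3 and H3, all over 0.1, so a fit with the number as a block was run as an alternative. No label states a pairing, and these values do not establish it. C1 correlated more with H2 (0.7) than with H1, and C2 more with H1 (0.288) than with H2. Deviations from a group mean cancel within the group, so an outlying C3 and H3 also raise the correlations between the other libraries. No 2 libraries of a group matched within sampling noise, since the chi-square per degree of freedom was 8.79 or more in each pair. Other alternatives were DESeq2 1.42.0, RLE factors, library sizes alone, other filters, all 9 libraries in one fit, a robust fit, limma-voom and leaving out each library. After the data were seen, limma-voom with library quality weights, fits without C3 and H3, and an immediate early gene list were added. Alternatives that concern pseudocounts of normalised values did not apply to counts.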

Results

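Polyadenylated RNA of larval zebrafish was sequenced in 9 libraries, 3 per group, after 7 days in vehicle, 0.1 µg/L or 10 µg/L of PFDoDA. The series title states that the study asks how this compound acts on the larvae. The counts per library lay between 12128785 (L3) and 13791087 (C3). Libraries C3 and H3 differed from the other 7 in composition. Genes with a count numbered 20148 in C3 and 21995 in H3, against 21720 in C2 and 23456 to 23758 in the remaining 6. The 100 most abundant genes held 52.5% of the counts in C3 and 46.1% in H3, against 28.5% to 34.2% in the others. Cytosolic ribosomal protein genes held 21.7% and 13.6%, against 6.65% to 9.21%. Exocrine pancreas enzymes held 1.6% and 1.79%, against 0.19% to 0.495%. The TMM factors of C3 and H3 were 0.516 and 0.676, and those of the others 1.02 to 1.24. The first principal component, with 64.4% of the variance, had its highest values in these 2 libraries. C3 and H3 also differed from each other. Mitochondrially encoded genes held 3.98% of the counts in C3, the lowest share, and 8.06% in H3, the highest. On the second component, with 13.3% of the variance, C3 lay at 49 and H3 at -61.5.

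**Figure D1:**
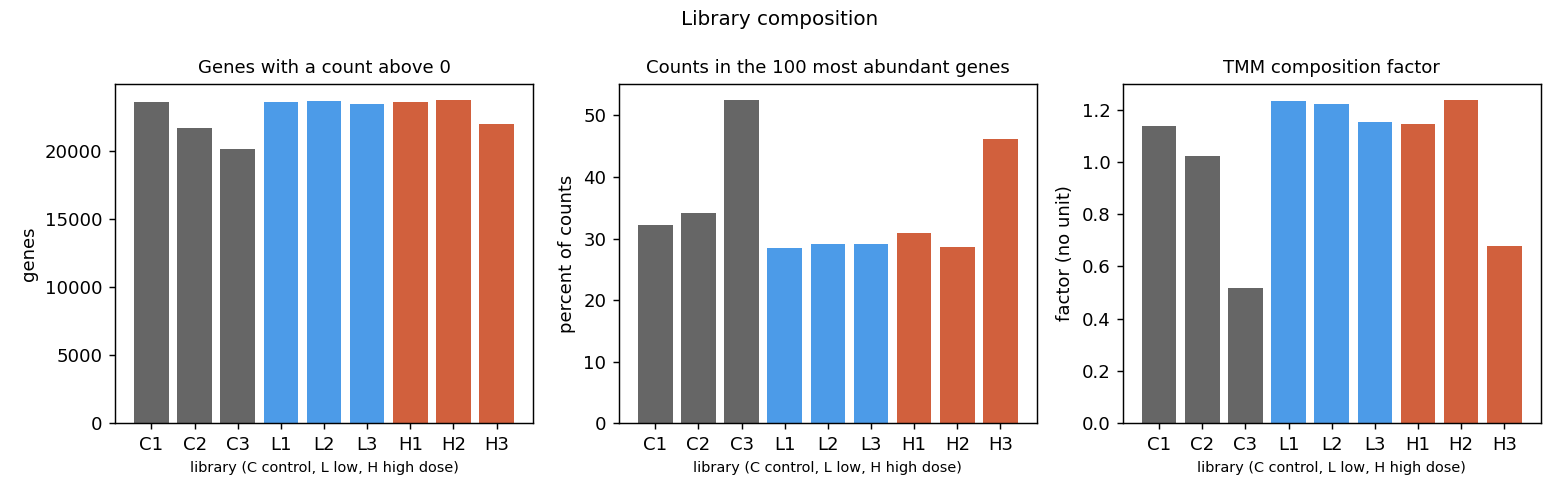
Genes with a count above 0, percent of counts in the 100 most abundant genes, and TMM factor (bars, 1 per library) for control (C, grey), low-dose (L, blue) and high-dose (H, orange) libraries. C3 (52.5%) and H3 (46.1%) have the highest share in the 100 most abundant genes and the lowest TMM factors (0.516 and 0.676).

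The comparison of 0.1 µg/L with vehicle asks which transcripts differ at the lower dose. Transcripts of sterol synthesis and cell division were higher in the low-dose libraries, and those of digestive enzymes were lower, as list calls of camera with its preset correlation. Each of these calls was lost with an estimated correlation (adjusted p = 0.427 with an estimated correlation for all 3 lists). With edgeR 0 of 19155 genes passed the adjusted threshold. An unadjusted p under 0.05 was found for 955 genes, where 958 are expected by chance. DESeq2 called 6 genes and limma-voom 0. The smallest adjusted p was 0.886, shared by the genes named in this comparison. The groups did not overlap in 13.2% of genes, where chance gives 10%.

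The gene with the smallest p was zgc:113054 (chromosome 6, 43450221 to 43474757, GRCz11), at 22.8 ± 2.67 CPM in controls and 66.3 ± 5.49 CPM at the low dose (SD, n = 3), a log2 difference of 1.54 ± 0.25 (SE). Its neighbour eevs (chromosome 6, 43438074 to 43449013), which encodes the enzyme for the first step of gadusol synthesis, came next. It had 21 ± 8.77 CPM in controls and 82.9 ± 12.1 CPM at the low dose, a log2 difference of 1.99 ± 0.37. Also higher were wdr76 (1.49 ± 0.33), the endoplasmic reticulum chaperone dnajb11 (1.33 ± 0.31) and 2 mevalonate pathway enzymes given with their list. The values of nosip (-2.54 ± 0.51), si:dkey-221j11.3 (-1.73 ± 0.39), the chitinase chia.3 (-2.16 ± 0.50) and the immediate early transcription factor egr2a (-3.55 ± 0.82) were lower. None of these 10 genes passed the adjusted threshold in edgeR, and each had groups that did not overlap.

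By camera with its preset correlation, 21 of 37 lists passed, 4 higher and 17 lower. With the correlation estimated per list 0 passed (smallest adjusted p = 0.427), and fry passed 0, with a smallest adjusted p of 0.52 and 2 lists at an unadjusted p under 0.05. Cholesterol synthesis and uptake rose by a median of 0.91 on the log2 scale over 27 members (camera adjusted p = 3.71e-08; adjusted p = 0.427 with an estimated correlation), with 22 members higher and 9 of them at an unadjusted p under 0.05. Adjusted over the list alone 2 members passed, and 0 over all genes. They were fdps, farnesyl diphosphate synthase, at 23.9 ± 2.98 and 56.5 ± 12.1 CPM (SD, n = 3; log2 difference 1.24 ± 0.28), and hmgcs1, an early enzyme of the mevalonate pathway, at 32.9 ± 18.6 and 127 ± 32.6 CPM (1.94 ± 0.43). The count over the list alone was 0 without C2, L1, L2 or L3, 10 without C1 and 13 without C3. Cell cycle and DNA replication genes rose by a median of 1.01 over 59 members (adjusted p = 1.37e-18; adjusted p = 0.427 with an estimated correlation). Of these, 55 were higher, 30 at an unadjusted p under 0.05, and 0 passed either over the list alone or over all genes. The mitotic kinesin kif11 had a log2 difference of 1.92 ± 0.50 and the condensin subunit smc2 of 1.92 ± 0.53. The per-library medians of both lists were higher in each low-dose library than in each control.

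Exocrine pancreas enzymes fell by a median of 1.99 over 21 members, the largest list difference (adjusted p = 3.22e-15; adjusted p = 0.427 with an estimated correlation). All 21 were lower and 18 passed when adjusted over the list alone, against 0 over all genes. That count was 16 without C3, and 0 without L1, L2 or L3 and with all 9 libraries in one fit. Without C3 the median was -1 (camera adjusted p = 9.48e-16; adjusted p = 0.101 with an estimated correlation). The carboxypeptidase cpa1 had 108 ± 68 CPM in controls and 30 ± 1.88 CPM at the low dose (SD, n = 3; log2 difference -1.85 ± 0.44). The amylase amy2a had 539 ± 563 and 66.7 ± 7.5 CPM (-3.02 ± 0.73), and the bile salt-dependent lipase cel.1 had 352 ± 384 and 42.6 ± 7.18 CPM (-3.05 ± 0.76). Without C3 these log2 differences were -1.2, -1.68 and -1.6. In C3 the list median lay 2.80 above the mean of the 9 libraries, against -0.05 in C1 and 0.18 in C2.

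Intestine markers fell by a median of 0.49 (30 members; adjusted p = 2.95e-05; adjusted p = 0.427 with an estimated correlation), with chia.3 and the cathepsin ctsl.1 (-1.85 ± 0.52) as the members with the smallest p. Lens crystallins fell by 1.16 (46 members; adjusted p = 2.69e-14; adjusted p = 0.487 with an estimated correlation), with cryaa at -1.44 ± 0.41 and grifin at -2.09 ± 0.59. Ribosomal proteins fell by 1.18 (79 members; adjusted p = 6.02e-18; adjusted p = 0.575 with an estimated correlation), with rps15 at -1.81 ± 0.64 and rps12 at -2.21 ± 0.81. Without C3 the medians were -0.21, -0.36 and -0.26, and ctsl.1 stood at -1.11, cryaa at -0.93, grifin at -1.37 and rps12 at -0.53. In these lists 0 members passed over the list alone. Cartilage, bone and matrix genes rose by 0.27 (64 members; adjusted p = 0.00187; adjusted p = 0.682 with an estimated correlation), with hapln1a at 1.29 ± 0.43 and timp2b at 1.03 ± 0.39. Erythroid genes rose by 0.44 (34 members; adjusted p = 0.00449; adjusted p = 0.617 with an estimated correlation), with epb41b at 1.45 ± 0.58 and creg1, against the list's direction, at -2.33 ± 0.78. Neither of these 2 lists passed without C2 (-0.03 and 0) or without L3 (0.1 and 0.24), and erythroid genes did not pass without C1 (0.37). Without C3 their medians were 0.58 and 0.79 and creg1 stood at -0.93. Without L1 the cartilage median was 0.46, and without L3 hapln1a stood at 0.77.

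The other lists called lower were skeletal muscle (-0.42), phototransduction (-0.31), oxidative phosphorylation (-0.43), histones (-0.97), glucocorticoid response (-0.58), liver markers (-0.49), glycolysis and gluconeogenesis (-0.49), interferon response (-0.53), mitochondrially encoded genes (-0.30), epidermis and ionocytes (-0.31), apolipoproteins (-0.40) and oxidative stress (-0.40). Their adjusted p with an estimated correlation ran from 0.427 to 0.718. The list called glycolysis and gluconeogenesis here also holds fasting genes. Without C3 oxidative phosphorylation passed in the opposite direction (0.28, adjusted p = 0.802 with an estimated correlation). The interferon response (0.1), epidermis and ionocytes (0.11) and oxidative stress (0.19) turned without passing, and histones (-0.33), liver markers (-0.22) and apolipoproteins (-0.07) did not pass. Skeletal muscle (-0.15), glycolysis and gluconeogenesis (-0.1) and glucocorticoid response (-0.37) still passed without C3, at smaller medians. Without C1 the medians of oxidative stress (-0.7), oxidative phosphorylation (-0.81), the interferon response (-0.89), epidermis and ionocytes (-0.53), histones (-1.65) and phototransduction (-0.5) were larger in size. Without C2 this held for oxidative phosphorylation (-0.75), the interferon response (-0.88), epidermis and ionocytes (-0.54) and mitochondrially encoded genes (-0.56), while histones stood at -0.58. The interferon response was at -0.8 without L2, and epidermis and ionocytes at -0.49 without L3. Apolipoproteins (-0.29), oxidative stress (-0.3) and epidermis and ionocytes (-0.24) also did not pass without L1, nor mitochondrially encoded genes without C1 (-0.27). Lists of peroxisome proliferator-activated receptor (PPAR) targets and fatty acid oxidation (adjusted p = 0.872), xenobiotic metabolism (0.476), fatty acid synthesis (0.785), bile acids (0.766) and the thyroid axis (0.0667) did not pass camera. Without C3, however, 5 lists not called with it passed. These were PPAR targets and fatty acid oxidation (0.3, adjusted p = 0.0064) and heat shock and unfolded protein response (0.25, 0.00209) as higher, and neurotransmission (-0.25, 9.11e-05), the thyroid axis (-0.25, 0.0189) and the circadian clock (-0.17, 0.0389) as lower. Their adjusted p with an estimated correlation without C3 ran from 0.679 to 0.759. Of the 20 genes always examined, 18 were tested, 6 were higher and 12 lower, and 0 passed. Besides hmgcs1, an unadjusted p under 0.05 was found for cdkn1a (0.72 ± 0.31), cyp3a65 (-1.09 ± 0.37), fabp10a (-1.83 ± 0.67) and pdk2b (-1.60 ± 0.57). Without C3 fabp10a stood at -0.7 and pdk2b at -1.01.

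**Figure D2:**
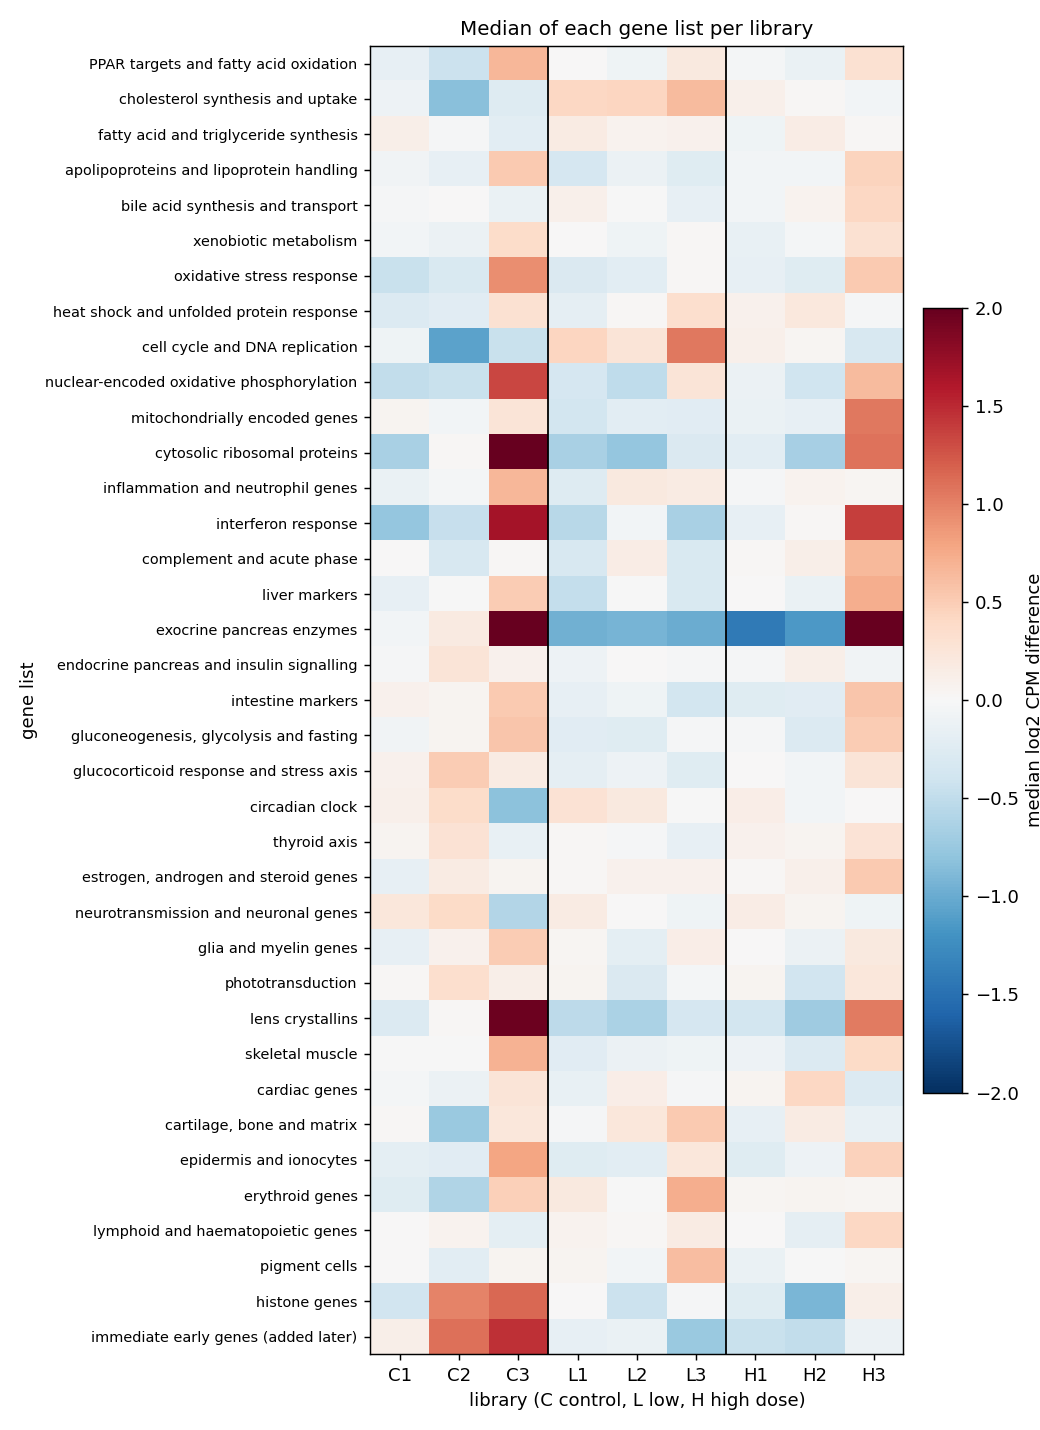
Median log2 CPM of each gene list drawn (rows) in each library (columns), as the difference from each gene's mean over the 9 libraries (colours end at -2 and 2; the immediate early genes were added after the data were seen). Exocrine pancreas enzymes are at 2.80 in C3 and 2.63 in H3, and between -1.42 and -0.93 in the other dosed libraries, while cholesterol synthesis lies at 0.42 to 0.64 in the low-dose libraries and at -0.84 to -0.10 in controls.

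The comparison of 10 µg/L with vehicle asks the same of the higher dose. Among the genes with the smallest p were fosab, egr2a, egr4 and npas4a, transcription factor genes that are rapidly induced by stimuli, each lower in all high-dose libraries than in each control, without passing the adjusted threshold. Sterol synthesis and cell cycle lists were higher, as list calls of camera with its preset correlation. Both calls were lost with an estimated correlation (adjusted p = 0.789 and adjusted p = 0.882 with an estimated correlation), and neither list passed without C2 (0.22 and 0.14). With edgeR, 0 of 19012 genes passed, and the smallest adjusted p was 1. An unadjusted p under 0.05 was found for 138 genes, where 951 are expected by chance. DESeq2 called 3 genes and limma-voom 0. With the replicate number as a block edgeR called 0 genes (264 at an unadjusted p under 0.05; smallest adjusted p 0.0622, fosab), and 11 lists passed camera. The groups did not overlap in 4.95% of genes, where chance gives 10%.

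The transcription factor gene fosab (chromosome 20, 46552311 to 46554440) had 265 ± 190 CPM in controls and 16.3 ± 8.07 CPM at the high dose (SD, n = 3), a log2 difference of -4.03 ± 0.73 (SE). For egr2a (chromosome 17, 43663504 to 43677471) the values were 25.1 ± 18.8 and 1.51 ± 0.151 CPM (-4.04 ± 0.75). The kinase gene sik1 differed by -1.99 ± 0.41, the matricellular gene ccn1 by -2.09 ± 0.43, the neuronal activity-induced gene npas4a by -1.49 ± 0.32 and egr4 by -2.07 ± 0.49. The tissue factor gene f3b (-2.82 ± 0.66), the cyclooxygenase gene ptgs2b (-2.30 ± 0.54) and the histone gene copy zgc:154164 (-4.54 ± 1.01), uncertain because near-identical copies may share reads, were also lower. Angiotensinogen, agt, was higher at 15.4 ± 3.42 and 41.4 ± 7.98 CPM (SD, n = 3; 1.43 ± 0.33). None of these 10 passed the adjusted threshold, and each had groups that did not overlap. At the low dose fosab differed from controls by -2.70 ± 0.90 and sik1 by -1.73 ± 0.42, also short of the threshold. The pair eevs (1.06 ± 0.54) and zgc:113054 (0.69 ± 0.38) overlapped the controls at the high dose, through H2, and stood at 0.7 and 0.37 without H3.

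By camera 10 of 37 lists passed, 3 higher and 7 lower. With an estimated correlation 0 passed (smallest adjusted p = 0.789), and fry passed 0 (smallest adjusted p = 0.971), with 0 at an unadjusted p under 0.05. Without C3 and H3, 18 passed, 7 of them among these 10 with the same direction. Newly called higher were erythroid genes (0.54), the interferon response (0.41), heat shock and unfolded protein response (0.34) and cartilage, bone and matrix (0.27). So were cardiac genes (0.25), oxidative phosphorylation (0.2) and PPAR targets and fatty acid oxidation (0.2). Newly called lower were intestine markers (-0.28), glucocorticoid response (-0.27), the circadian clock (-0.2) and neurotransmission (-0.16). No list passed in that fit with an estimated correlation (smallest adjusted p = 0.649). Cholesterol synthesis rose by a median of 0.40 (27 members, 21 higher; adjusted p = 4.27e-05; adjusted p = 0.789 with an estimated correlation), with hmgcs1 at 1.1 ± 0.46 and mvda, mevalonate diphosphate decarboxylase, at 0.89 ± 0.49. Cell cycle genes rose by 0.39 (59 members, 50 higher; adjusted p = 5.35e-09; adjusted p = 0.882 with an estimated correlation), with the ribonucleotide reductase gene rrm1 at 1.00 ± 0.40 and cdk1 at 1.09 ± 0.57. Complement and acute phase genes rose by 0.41 (31 members, 24 higher; adjusted p = 4.27e-05; adjusted p = 0.789 with an estimated correlation), with c7b at 1.5 ± 0.55 and c4b at 1.5 ± 0.59. Without C2 none of these 3 lists passed, at medians of 0.22, 0.14 and 0.13, and without H3 complement did not pass (0.14). Without C1 hmgcs1 stood at 1.68 and mvda at 1.42, and without H2 c4b stood at 0.99.

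Histone genes fell by 0.8 (17 members; adjusted p = 5.73e-07), with copies of hist1h4l at -3.93 ± 1.00 and zgc:112234 at -3.83 ± 1.05. Their adjusted p was 0.789 with an estimated correlation, and the list did not pass without C3 (-0.05). Its median was -1.99 without C1 and -1.66 without H3, and zgc:112234 stood at -2.34 without C2. Exocrine pancreas enzymes fell by 0.99 (22 members, 17 lower; adjusted p = 0.000176; adjusted p = 0.96 with an estimated correlation), with ptf1a at -0.84 ± 0.85 and prss59.2 at -0.95 ± 1.29. The amylase amy2a had 1049 CPM in H3 and 1071 in C3, against 47.9 in H1, 64.6 in H2, 159 in C1 and 229 in C2 (-0.33 ± 1.24), and cel.1 had 783 in H3 and 716 in C3, against 30.4 to 135 in the others (-0.16 ± 1.3). With the replicate number as a block the log2 differences of amy2a and cel.1 were -1.21 and -1.14. Both turned without C3, H1 or H2 (amy2a 0.99, 0.19 and 0.17; cel.1 1.27, 0.37 and 0.36), and prss59.2 without C3 (1.08). Without H3 they stood at -3.11, -3.18 and -3.1, and prss59.2 at -0.47 without H1 and -0.5 without H2. Without C1 amy2a was at -0.75 and cel.1 at -0.58. Without C2 amy2a was at -0.68, cel.1 at -0.54, prss59.2 at -1.43 and ptf1a at -0.03, and ptf1a stood at -0.43 without H2 and -1.59 without H3. The pancreas list did not pass without C3 (0.06), H1 (-0.23) or H2 (-0.38), and its median was -2.28 without H3 and -1.33 without C3 and H3 (camera adjusted p = 1.58e-21; adjusted p = 0.649 with an estimated correlation). Lens crystallins (-0.59), ribosomal proteins (-0.45), phototransduction (-0.24) and skeletal muscle (-0.25) also fell, with adjusted p = 0.96 each with an estimated correlation. Without C3 ribosomal proteins passed in the opposite direction (0.4), while lens crystallins (0.1) and skeletal muscle (0.07) did not pass. Without H2 none of these 4 passed (crystallins -0.3, ribosomal proteins -0.1, phototransduction -0.07, skeletal muscle -0.14), nor phototransduction without C2 (-0.17) or skeletal muscle without H1 (-0.19). Without H1 crystallins stood at -0.39. Without C1 or H3 the medians were larger in size, at -1.02 and -1.2 for crystallins, -1.06 and -1.01 for ribosomal proteins, -0.45 and -0.41 for phototransduction and -0.43 and -0.45 for skeletal muscle, and ribosomal proteins stood at -0.7 without C2. In all 10 lists 0 members passed over the list alone. Of the 20 genes always examined, 18 were tested, 6 were higher and 12 lower. One, hmgcs1, had an unadjusted p under 0.05 and 0 passed.

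**Figure D3:**
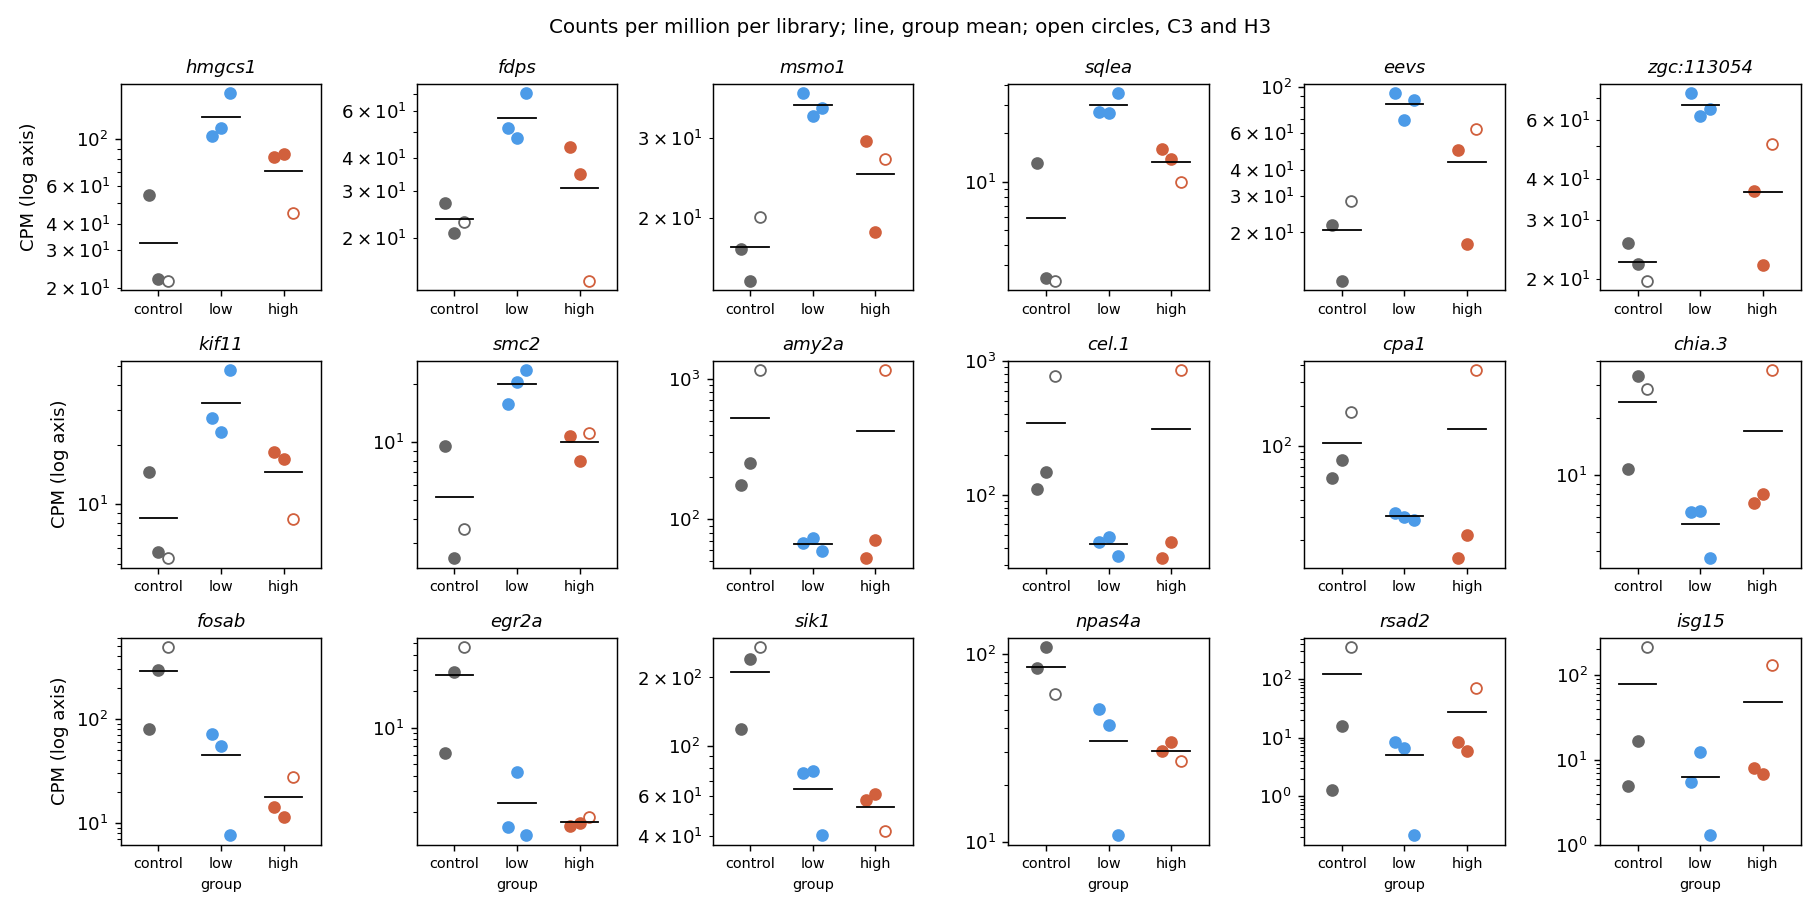
CPM per library, scaled over all 9 libraries, on log axes for 18 genes. Filled circles are libraries, open circles are C3 and H3, and lines mark group means. The 3 low-dose libraries lie above each control for hmgcs1 and eevs, fosab is at 11.4 to 27.9 in the high-dose libraries against 80.7 to 488 in controls, and amy2a stands at 1150 in both C3 and H3.

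The comparison of 10 µg/L with 0.1 µg/L tests the difference between doses directly, without the controls. Sterol synthesis and cell cycle lists were lower at the high than at the low dose, while liver, complement, interferon and ribosomal protein lists were higher, as list calls of camera with its preset correlation. With an estimated correlation 0 of the 37 lists passed (adjusted p from 0.544 to 0.616 with an estimated correlation for these 6 lists). Without H3 the higher lists still passed, with smaller medians (liver 0.22, complement 0.27, interferon 0.28, ribosomal proteins 0.13). With edgeR 0 of 19299 genes passed (smallest adjusted p = 0.97). An unadjusted p under 0.05 was found for 431 genes, where 965 are expected by chance, DESeq2 called 0 and limma-voom 0. The smallest p values belonged to the autophagy receptor gene calcoco2 (1.25 ± 0.25), nudcd2 (2.01 ± 0.41), the squalene epoxidase gene sqlea (-1.16 ± 0.25), arl2 (-1.70 ± 0.38), the anchoring fibril collagen gene col7a1 (-1.22 ± 0.28), si:ch211-81a5.8 (1.22 ± 0.29), the cone opsin gene opn1mw2 (1.01 ± 0.24), si:ch211-198c19.3 (1.68 ± 0.43), pinx1 (0.90 ± 0.23) and zgc:154164 (-1.94 ± 0.50), none past the threshold. In CPM, sqlea had 32.6 ± 5.22 at the low and 14.5 ± 3.31 at the high dose (SD, n = 3). The pair eevs (-0.92 ± 0.42) and zgc:113054 (-0.85 ± 0.30) was lower at the high dose, without passing, and eevs stood at -0.55 without H2. Of the 20 genes always examined, hmgcs1 (-0.84 ± 0.30) had an unadjusted p under 0.05, and of 18 tested 8 were higher and 10 lower.

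By camera 19 of 37 lists passed, 15 higher and 4 lower, 0 with an estimated correlation (smallest adjusted p = 0.544), and fry passed 0 (smallest adjusted p = 0.28; 3 at an unadjusted p under 0.05). Cholesterol synthesis fell by a median of 0.43 (27 members, 24 lower; adjusted p = 1.61e-07; adjusted p = 0.544 with an estimated correlation), with lss, lanosterol synthase, at -0.75 ± 0.22 beside sqlea. Cell cycle genes fell by 0.58 (61 members, 57 lower; adjusted p = 8.33e-16; adjusted p = 0.563 with an estimated correlation), with smc2 at -0.99 ± 0.26 and the spindle gene tpx2 at -0.93 ± 0.26. For both lists each high-dose library lay below each low-dose library, and without H3 the medians were -0.45 and -0.44. The cholesterol median was -0.27 without H2, and the cell cycle median -0.37 without L3. Complement (0.52), liver markers (0.54), the interferon response (0.76) and ribosomal proteins (0.69) rose, with adjusted p of 1.79e-08, 2.65e-08, 1.66e-08 and 3.79e-17, and 0.544, 0.563, 0.563 and 0.616 with an estimated correlation. Their leading members were c3a.4 (1.93 ± 0.49), lect2l (0.89 ± 0.25), ttr (1.08 ± 0.30), tat (1.76 ± 0.60), psmb8a (1.86 ± 0.61), stat1b (2.6 ± 0.98), rpl12 (1.63 ± 0.55) and rps12 (1.29 ± 0.58). Without H3 the list medians were 0.27, 0.22, 0.28 and 0.13, and tat stood at 0.76, stat1b at 0.56, rpl12 at 0.68 and rps12 at 0.24. The interferon median was 1.31 without H1 and 1.22 without H2, and that of ribosomal proteins 1.04 without H2.

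The other lists called higher were lens crystallins (0.53), oxidative phosphorylation (0.29), mitochondrially encoded genes (0.60), apolipoproteins (0.35), exocrine pancreas enzymes (1.09), intestine markers (0.22), glycolysis and gluconeogenesis (0.23), the thyroid axis (0.19), glucocorticoid response (0.26), skeletal muscle (0.13) and oxidative stress (0.25). Cartilage, bone and matrix (-0.25) and erythroid genes (-0.22) were called lower. Their adjusted p with an estimated correlation ran from 0.544 to 0.712. Without H3 the pancreas median was -0.31 and passed in the opposite direction (adjusted p = 0.556 with an estimated correlation). The medians of lens crystallins (-0.08), oxidative phosphorylation (-0.07), intestine markers (-0.07), skeletal muscle (-0.02) and oxidative stress (-0.07) turned without passing. Mitochondrially encoded genes (0.1) and glycolysis and gluconeogenesis (0.05) did not pass without H3, and apolipoproteins (0.13), the thyroid axis (0.03) and glucocorticoid response (0.12) passed at smaller medians. Some lists passed camera without H3 and not with it. They were histones (-0.31, adjusted p = 0.000117), cardiac genes (0.29, 0.00121), neurotransmission (0.1, 0.00227), pigment cells (-0.29, 0.0052) and endocrine pancreas and insulin signalling (0.09, 0.0478). Their adjusted p with an estimated correlation without H3 ran from 0.556 to 0.632. Without H1 the medians of pancreas enzymes (1.82), intestine markers (0.43), glucocorticoid response (0.4), the thyroid axis (0.3) and skeletal muscle (0.21) were larger. Without H2 those of oxidative phosphorylation (0.52), intestine markers (0.4), glycolysis and gluconeogenesis (0.4), glucocorticoid response (0.42), lens crystallins (0.86) and skeletal muscle (0.27) were larger. Without L3 this held for oxidative stress (0.38), oxidative phosphorylation (0.51), glycolysis and gluconeogenesis (0.37) and skeletal muscle (0.23), while cartilage, bone and matrix stood at -0.14. Cartilage, bone and matrix stood at -0.4 without L1, and without L2 oxidative phosphorylation at 0.17 and erythroid genes at -0.42. Calls also ended for oxidative stress without L1 or L2 (0.23 each), skeletal muscle without L1 (0.13), intestine markers (0.23), glucocorticoid response (0.29) and erythroid genes (-0.01) without L3, and erythroid genes without H1 (-0.28) or H2 (-0.23). In this comparison 0 members of any list passed over the list alone.

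The log2 fold changes of the 2 doses against the shared controls were correlated across 18783 genes (Pearson r = 0.729, Spearman rho = 0.71), and genes are not independent replicates. Simulated unchanged groups against shared simulated controls gave a mean r of 0.506 (SD 0.0069 over 100 sets) and a mean rho of 0.476. The covariance was 0.219 against 0.188 simulated, a difference of 0.031, and 76.1% of genes had the same sign against 66.9%. The simulation draws genes independently and all 9 libraries from a common mean profile, so it leaves out the outlying composition of C3 and H3. When the 9 libraries were regrouped at random 100 times, which keeps their structure, 17 regroupings gave an r at least as high, and the highest was 0.956. Without C1, C2 or C3 the observed r was 0.907, 0.79 and 0.661. Both comparisons had 0 calls, so 0 were shared. The 2 comparisons share their controls, which are too few to be divided.

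In the authors' deposited table, 6 genes had an adjusted p under 0.05 at the low dose, 2 higher and 4 lower, and 3 at the high dose, all lower. At the low dose the authors' deposited table lists zgc:113054 (log2 fold change 1.52, adjusted p = 0.000305), eevs (1.97, 0.00853), fosl1a (-3.60, 0.00853), amy2a (-3.03, 0.0205), cel.1 (-3.06, 0.028) and bicdl2l (-3.07, 0.0344). At the high dose the authors' deposited table lists fosab (-4.05, 7.91e-05), egr2a (-4.06, 0.000174) and zgc:154164 (-4.58, 0.00615). The edgeR values for fosl1a and bicdl2l at the low dose were -3.59 ± 0.85 and -3.06 ± 0.78 (adjusted p = 0.886), and bicdl2l stood at -1.8 without C3. Across genes the fold changes of the authors' deposited table and those computed here correlated at a rounded r of 1 in both comparisons. DESeq2 run here gave the same counts of 6 and 3.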

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

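Chosen after the data were seen were limma-voom with library quality weights and the fits without C3 and H3. The 0 gene calls per comparison from edgeR were kept under RLE factors, library sizes alone, both other filters, all 9 libraries in one fit, the robust fit, limma-voom, each left-out library and, for the high dose, the replicate block (0 genes) and the fit without C3 and H3. DESeq2 called 6 genes at the low and 3 at the high dose, and the cause was not tested. With quality weights limma-voom called 3796 genes at the low dose, 9 at the high dose and 0 between doses. In the low-dose comparison C2 had most weight among controls (3.69, against 0.369 for C1 and 0.115 for C3). L1 had 3.22, L2 2.42 and L3 0.817. Another split of the same 6 libraries (C1, L2 and L3 against the rest) gave 6088 calls, so as many calls can come from a split that mixes the groups. With quality weights, C1, C2 and H2 against the rest gave 2498 calls in the high-dose comparison. Between doses, L1, L2 and H2 against the rest gave 8.

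List calls were 0 in all 3 comparisons with an estimated correlation. The replicate block gave 11 lists at the high dose. Leaving out 1 library gave 8 to 17 lists at the high dose (17 without C3), and leaving out C3 and H3 gave 18. Library sizes alone shifted the median of all genes from 0.11 to 0.619 at the low dose, from 0.047 to 0.274 at the high dose and from -0.037 to -0.327 between doses. The list medians, given relative to it, kept their direction. Scaling factors move all genes of a library nearly alike, so this does not test the lists. The correlation of the doses was 0.744 for genes of at least 5 CPM, 0.661 to 0.907 leaving out 1 control and 0.813 without C3 and H3.

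Among named genes and called lists, no setting other than a left-out library reversed a direction. For genes, 732 of these 779 values kept their side of the threshold and 47 newly passed, and for lists 64 of 120 kept it and 56 no longer passed. With a library left out, 485 of 492 gene values and 249 of 300 list values were the same, 39 list values no longer passed, and 7 gene and 12 list values reversed. A list counts as reversed where camera's direction turned. The ranges over left-out libraries that include a reversal were, at the low dose, -0.7 to 0.19 for oxidative stress, -0.81 to 0.28 for oxidative phosphorylation, -0.89 to 0.1 for the interferon response and -0.54 to 0.11 for epidermis and ionocytes, each reversed without C3. At the high dose they were -1.06 to 0.4 for ribosomal proteins, -1.2 to 0.1 for lens crystallins and -3.1 to 1.08 for prss59.2, reversed without C3, and -3.11 to 0.99 for amy2a and -3.18 to 1.27 for cel.1, reversed without C3, H1 or H2. Between doses they were -0.07 to 0.38 for oxidative stress, -0.07 to 0.52 for oxidative phosphorylation, -0.31 to 1.82 for exocrine pancreas enzymes, -0.07 to 0.43 for intestine markers, -0.08 to 0.86 for lens crystallins and -0.02 to 0.27 for skeletal muscle, reversed without H3. The medians of 4 further lists reached or crossed 0 while camera kept its direction and no longer passed. They ranged from -0.03 to 0.58 for cartilage, bone and matrix and from 0 to 0.79 for erythroid genes at the low dose (lowest without C2), and from -2.28 to 0.06 for exocrine pancreas enzymes and from -0.45 to 0.07 for skeletal muscle at the high dose (highest without C3). The causes were not tested beyond the libraries named. The planned pseudocounts were not run, since they apply to normalised values only. Depth was similar in all libraries, and whether depth or the spread between libraries limits the gene tests was not tested.

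With 10 splits of 6 libraries (4 that part all pairs, for the high dose) no share under 0.05 can be reached. Gene calls were 0 in the real and in all other splits of each comparison (10 of 10, 4 of 4 and 10 of 10). List calls at the low dose were 21, with 22 as the highest of the other splits (2 of 10 gave as many). At the high dose they were 10, with 17 as the highest (3 of 4), and between doses 19, with 19 as the highest (3 of 10). No label states a pairing, and among all splits of the high-dose comparison the highest was 22 (C1, C2 and H1 against the rest).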

Other observations

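The tests of the length trend, the medians without C3 and H3, the shared replicate number, the order of the doses, the liver and intestine lists and the summed pancreas counts were chosen after the result was seen, as was the immediate early gene list. The test without the 500 most abundant genes was not.

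Of 35 measured immediate early genes (transcription factors and effectors induced within minutes of a stimulus), 35 were lower than controls at the low dose and 31 at the high dose, 23 and 21 of them at an unadjusted p under 0.05, with 0 past the adjusted threshold. The medians were -1.33 and -1.11 on the log2 scale relative to all genes. With an estimated correlation camera gave an unadjusted p of 0.0573 and 0.0181, outside the adjustment of the fixed lists, and because the list was chosen from these libraries this is no independent evidence. Between doses the median was 0.03, with an unadjusted p of 0.825. The per-library medians were 0.11 in C1, 1.1 in C2 and 1.46 in C3, and -0.75 to -0.11 in the dosed libraries, so C1 lay close to them. Without C3 and H3 the estimated correlation gave an unadjusted p of 0.147 and 0.172. Members that other fixed lists hold include sik1 (gluconeogenesis, glycolysis and fasting), dusp1 (glucocorticoid response) and atf3 (heat shock and unfolded protein response). For fosab C1 had 80.7 CPM and L1 72.4, while C3 had 488.

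The first pattern is this lower level of immediate early genes. Whether the profile shared by C3 and H3 is the cause stays open. The list median was 1.46 in C3 but -0.11 in H3, the highest value of the dosed range. Without both libraries the medians were still -1 at each dose, but this rests mainly on C2, at 1.1. C1 lay only 0.25 above the highest remaining dosed library, while C1 and C2 differed by 0.99. C2 also leaned towards C3 and H3 in composition. It had 21720 detected genes, against 21995 in H3. Among the libraries other than C3 and H3, it had the highest ribosomal protein share (9.21%) and the lowest TMM factor (1.02). Exposure to the compound stays open too. The high-dose libraries did not lie below the low-dose ones (difference of mean medians 0), which would not exclude a response already complete at 0.1 µg/L. These genes also respond to handling, and the order in which the tubes were collected and frozen is not in the labels, so exposure to the compound and handling cannot be told apart.

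The second pattern is the lower level of exocrine pancreas enzymes in L1, L2, L3, H1 and H2 than in each control, with H3 as high as C3. The pattern sets H3 aside, so the remaining dosed libraries must lie below C1 and C2 once C3 and H3 are left out. That direction was fixed and does not test the profile shared by C3 and H3, which stays open. In size, the median without both was -1 at the low and -1.33 at the high dose. The remaining dosed libraries lay at least 0.88 below C1 and C2, against a range of at most 0.27 within a group. That range has few libraries behind it without C3 and H3. A smaller share of digestive organs is argued against as the whole cause, since liver and intestine markers lay at least 0.78 above the pancreas median, but intestine markers passed camera as lower without both (-0.21 and -0.28; adjusted p = 0.679 and 0.649 with an estimated correlation), so a part is not excluded. Reads moved between listed paralogs would leave the sum over the list in place. The sum was lower by 1.14 on the log2 scale (1654 to 2187 CPM, against 3976 in C1 and 4837 in C2). Movement among listed copies alone therefore does not account for it. The counting options are not given, so reads discarded or counted for unlisted copies stay open. A change in the pancreas, or in feeding, before sampling is a candidate explanation that the design does not test further, and 2 controls are left to carry it.

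The third pattern is that C3 and H3 stand apart, with rsad2 at 355 CPM in C3 and 69.9 in H3 (0.214 to 16.2 in the others) and isg15 at 212 and 131 (1.29 to 16.5), besides ribosomal, pancreatic and crystallin transcripts. The difference was not confined to the 500 most abundant genes. Without them the median correlation with the other libraries was 0.786 in C3 and 0.854 in H3, against at least 0.914 in the rest. Whether abundant genes taking the counts caused it stays open. The correlation covers 19174 genes, so leaving out 500 can change it little, and it does not restore the depth those genes took. A loss of long transcripts stays open: at matched abundance the rank correlation of deviation with gene length was -0.244 in C3 and -0.243 in H3 against -0.18 in L3, but without matching L3 had the lowest (-0.2, against -0.179 and -0.178). Whether the number 3 marks a shared tank or day stays open (correlation of deviations 0.634), and that origin and a chance pair of libraries cannot be told apart. The dose does not separate them, since C3 is a control.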
